A study of Mus with 2 samples.

How the data were processed

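The study measured single epithelial cells of the mouse distal ileum. Per the labels, cells were isolated by flow cytometry sorting and sequenced with inDrops, a droplet method that tags each RNA molecule with a cell barcode and a molecular identifier. One sample came from mice in which diphtheria toxin A was expressed from the nociceptor-directed Nav1.8 Cre driver, which removes nociceptors, the sensory neurons that respond to noxious stimuli. The other sample came from littermates that carried the toxin allele without Cre. Each sample pooled 3 mice, and each genotype had 1 sample. Per the deposited library sheet, the mice were males of 8 weeks, and the cells were split over 4 sub-libraries of the control and 3 of the nociceptor-ablated genotype. That sheet gave 2500 cells for each control sub-library (10000 in all) and between 2500 and 3500 for each of the others (8500 in all). The authors mixed each of these sub-libraries into the sequencing pool at 12.86 percent, per the deposited sheet. Sub-libraries of 1 pool of mice are not replicates, and no table used here separates them.

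The submitters' processing notes name Cell Ranger, Seurat, DESeq2 version 1.30.1 and the genome build mm10. The cell type sheets are labelled with the last of these tools, and their fold change column bears the name that Seurat gives it. The marker table is labelled LR. Beyond these labels, which tool made which column is not given in the sources used here. Nor do they say how cells were filtered, how doublets were treated or how cell types were assigned. The authors deposited 1 sheet of fold changes for each of 5 cell types (enterocytes, stem cells, goblet cells, enteroendocrine cells and tuft cells) and 1 table of cluster markers. Per the file headers, each cell type sheet holds a log2 fold change of mean expression between a first and a second group of cells, and the share of cells of either group in which the gene was detected. The deposited sheets also hold a p-value for each gene, computed by the authors over single cells. Those p-values do not measure the spread between animals, so none is printed and no gene was chosen by one. Their order among genes was used only in checks on the zero point of the fold changes and on how the p-values were made. These checks are given in the Results and in the closing sections.

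No sheet says which genotype is the first group, nor that the order is the same in every sheet. The groups are therefore called group 1 and group 2, in the order of the sheets, and no value was used to assign a genotype to either. A fold change is group 1 over group 2: among genes whose detection differed by over 10 percentage points, the sign of the fold change and of the detection difference were equal for between 96.4% (enteroendocrine cells) and 100% (enterocytes and stem cells). In the enteroendocrine and tuft sheets, 245 and 2815 genes had a detection share of 0 in one group and still a finite fold change, so the scale includes an offset whose size is not given in the sources used here. Fold changes of weakly detected genes are therefore compressed. Every gene in the sheets was detected in at least 10.0% of the cells of one group, so genes under that share are not analysed here. The number of cells and of molecules behind each sheet is not given in the sources used here, and cell numbers were not worked out from the decimals of the shares, so no interval over cells was computed. The smallest detection share above 0 was 3.8% and 5.4% (groups 1 and 2) for enterocytes, 3.4% and 6.3% for stem cells, 3.1% and 3.7% for goblet cells, 2.9% and 2.5% for enteroendocrine cells and 5.6% and 14.3% for tuft cells.

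With 1 sample per genotype there is no test of genotype, and no standard error or count of changed genes is given. Before the data were examined, 38 gene lists and the rules for naming genes were fixed. The sheets give no mean expression, so the mean of both detection shares took its place wherever the rules called for mean expression. Genes were named by size: in each cell type the 10 highest and the 10 lowest log2 fold changes among genes at or above the median detection, without predicted gene models. Ramp1 and Muc2 were named wherever they were listed, as were up to 4 members of each list with the largest absolute fold change at or above the median detection, and the 5 leading genes of each cluster, of which 1 is not reported here. The same rule asked for Scn10a, Calcrl, Calca and Calcb, which are not analysed here. A list with at least 5 genes in a sheet was described by its median log2 fold change and by the percentile of that median among 10000 random lists of equal size matched over 10 bins of detection. A median under the 2.5th or over the 97.5th percentile is described as standing apart, which is a statement about these libraries and not a test of genotype. Lists of T cell, B cell, myeloid, fibroblast and muscle, endothelial, neuronal and glial, erythroid and sex-linked genes had fewer than 5 genes in every sheet and were not ranked. Members of a list were also counted above and below the median of all genes of their sheet. Fold changes were compared between cell types by Spearman correlation across genes at or above the median detection in both sheets. These correlations are across genes, which are not independent replicates, and all cell types come from the same 2 samples.

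The alternatives set before the data were examined were other detection floors, the mean in place of the median of a list, no matching of random lists, Pearson correlation, and only the 50 leading markers of each cluster. Another zero point for the fold changes was added after seeing the data. The list percentile was tested on simulated data, with 100 random lists of 20 genes per sheet. Unchanged lists stood apart 3 times in enterocytes, 5 in stem cells, 9 in goblet cells, 7 in enteroendocrine cells and 1 in tuft cells. Lists shifted by 1 SD of all fold changes of the sheet stood apart on the higher side 100 times of 100 in every sheet except that of enteroendocrine cells, with 98. The search for a zero point, tested on 15 simulated sets of p-values per sheet, missed the true value by at most 0.13 (log2, in enterocytes with 105 genes). Every gene had the same noise in these sets. For the list test, fold changes were shuffled across genes, which removes any link with detection and between genes of a list. Neither result therefore carries over fully to the sheets. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene positions are from a RefSeq table of GRCm38.p6, the assembly that mm10 names, matched by symbol: 8560 of 8990 symbols in the sheets had an entry. Near-identical family members, such as ribosomal protein genes and their pseudogenes, defensins, small proline-rich genes and the pair Hspa1a and Hspa1b, can share reads, and their separate values are uncertain.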

Results

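Epithelial cells of the distal ileum were profiled by droplet single-cell RNA sequencing in mice without Nav1.8-lineage nociceptors and in littermate controls, 1 pooled sample of 3 mice per genotype. The comparison asks how the loss of these neurons bears on gene expression in each epithelial cell type. Values per gene are those of the authors' deposited tables, with 3426 genes for enterocytes, 5403 for stem cells, 4537 for goblet cells, 5287 for enteroendocrine cells and 6765 for tuft cells. The tables do not state which genotype is group 1 and which is group 2, so each difference below is between 2 unnamed groups of cells and gives no direction of nociceptor loss. There is no replicate and no test of genotype, and the number of cells per sheet is not given in the sources used here. Detection shares took 19 and 8 distinct values (groups 1 and 2) in tuft cells and 35 and 41 in enteroendocrine cells, against 183 or more in each of the other sheets, so values of these 2 cell types are the coarsest.

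Over all listed genes, most fold changes were a little under 0 in each cell type. By the authors' deposited table, 21.4% of genes were higher in group 1 in enterocytes, 8.16% in stem cells, 27.3% in goblet cells, 35.3% in enteroendocrine cells and 31.3% in tuft cells. Genes detected less often in group 1 made up 72.3%, 91.8%, 71.4%, 67.4% and 68.6% in the same order. In tuft cells the smallest share above 0 was over the 10.0% limit in group 2 (14.3%) but not in group 1 (5.6%). The limit thus favoured genes detected in group 2 of that sheet. In stem cells the median detection was 16.6% in group 1 and 20.6% in group 2. Depth is not given in the sources used here. Per the deposited library sheet, the control made up 51.4% of the sequencing pool for 10000 cells and the nociceptor-ablated genotype 38.6% for 8500. The planned pool share per cell was thus higher in the control, and a difference in depth was not separated from these detection shares. The median log2 fold change of all genes was -0.03, -0.07, -0.04, -0.05 and -0.11 in the same order, and gene lists are set against these medians. A list on the higher side can therefore still have a median under 0. The zero point itself is uncertain: among genes detected in at least 70% of both groups, the share above 0 was 34.3% in enterocytes, and 79.0% lay above the fold change around which the deposited p-values are ordered. Among the 77 such genes of enteroendocrine cells, 57.1% lay above 0, with a median of 0.02. Of the 133 pairs of a list and a cell type, 48 stood apart from matched random lists, 36 on the higher and 12 on the lower side, where 6.65 would by chance if lists were independent sets of unrelated genes. They are not: 66 of the 919 genes in the lists given by name belong to more than 1 list, and genes of a list are often expressed together, so the pairs are not separate findings.

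In enterocytes, the absorptive cells of the villus, 2 antimicrobial lectins were among the 10 lowest genes in group 1, and genes of mature absorptive cells were among the 10 highest. The authors' deposited table gave Reg3g and Reg3b, secreted lectins that bind bacteria, log2 fold changes of -0.82 and -0.66, with detection in 100% of the cells of both groups. Reg3b lies on chromosome 6 from 78370885 to 78373466 and Reg3g on the same chromosome from 78466269 to 78468874 (mm10), both protein-coding. The other low genes in the authors' deposited table were Zc3h7a (-0.71), Itga9 (-0.70), Cdk8 (-0.64), Lgals2 (-0.62), Faxc (-0.59), Dmbt1 (-0.50), Arhgap24 (-0.50) and Safb (-0.49). Highest in the authors' deposited table was Apoa1, the apolipoprotein of high-density lipoprotein (chromosome 9, 46228630 to 46230469), by 0.50. It was followed in the authors' deposited table by Guca2b, the precursor of uroguanylin (0.42, detected in 81.3% of group 1 and 67.3% of group 2), Crip1 (0.35), the brush border cadherin Cdhr2 (0.30), mt-Co1 (0.26) and Muc3 (0.23). Alpi, the intestinal alkaline phosphatase (0.22), Clca4a (0.22), Nfkbia (0.21) and the carboxylesterase Ces2a (0.21) completed the 10 in the authors' deposited table.

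Absorptive gene groups lay together on the higher side in enterocytes. Of 40 enterocyte markers, 34 were above the median of all genes, and of 30 genes of the brush border and nutrient transport, 24 were, each list at percentile 100 of matched lists. Lipid absorption genes (18 of 27 above, percentile 99.9) included Apoc3 at 0.20, Npc1l1 at 0.19 and Fabp2 at 0.18 in the authors' deposited table. Retinoid and xenobiotic genes (11 of 16, percentile 99.8) and bile acid genes (7 of 10, percentile 98.7) were also high, with the ileal bile acid binding protein Fabp6 at 0.18 in the authors' deposited table. Stress and signalling lists stood apart on the same side: heat shock (7 of 10, percentile 99.8), immediate early genes (10 of 13, 99.8), nuclear factor kappa B and cytokine genes (6 of 9, 99.2) and interferon-stimulated genes (11 of 14, 98.8). Each of these had large members on both sides in the authors' deposited table, with Hspa1a at 0.19 and Hspa8 at -0.19, and Klf6 at 0.14 and Fos at -0.11. Nfkbia was at 0.21 and Ccl25 at -0.18, and Ifit1bl1 at 0.09 and Ifi27l2b at -0.20, in the authors' deposited table. Ribosomal protein genes lay low, with 59 of 66 below the median of all genes at percentile 0.0, as did nuclear genes of oxidative phosphorylation with 66 of 74 (percentile 0.03). The authors' deposited table listed Rpl8 at -0.38, Rps3 at -0.36 and Atp5g1 at -0.26. Goblet markers were low as well (6 of 10 below, percentile 2.49), including Spink4 at -0.29 and Agr2 at -0.28 in the authors' deposited table. Spink4 was detected in 50.2% of group 1 and 64.7% of group 2 enterocytes in the authors' deposited table. Free RNA from goblet cells was not separated from these values. With the mean in place of the median, the goblet, bile acid, interferon and nuclear factor kappa B lists no longer stood apart, and the bile acid list did not with a detection floor either. The list of antimicrobial genes did not stand apart (10 of 13 below, percentile 3.18). The remaining lists also stayed within the limits, up to percentile 96.7.

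**Figure D1:**
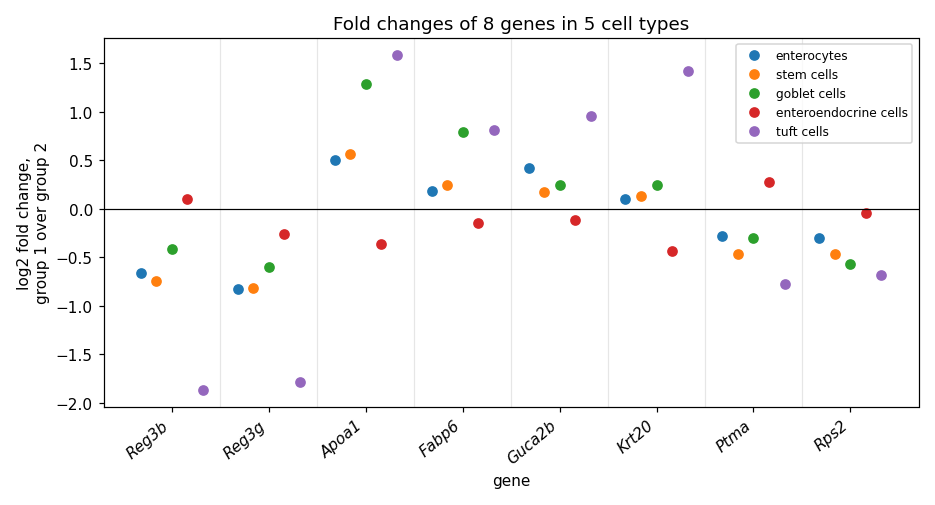
Log2 fold change (vertical axis, group 1 over group 2) of 8 genes (horizontal axis) in 5 cell types (colours), from the authors' deposited table, with 1 value per gene and cell type and no replicate error. Apoa1 was at 0.50 in enterocytes, 0.56 in stem cells, 1.29 in goblet cells and 1.59 in tuft cells, and at -0.36 in enteroendocrine cells.

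In the stem cell sheet, the lectins Reg3g and Reg3b, class II antigen presentation genes and proliferation genes were low in group 1. The authors' deposited table gave Reg3g -0.81 and Reg3b -0.75, each detected in at least 99.8% of cells of either group. Also low in the authors' deposited table were Faxc (-0.68), Ifitm3 (-0.57), Safb (-0.53), the histone variant gene H2afz (-0.47), Ptma (-0.47), the class II molecule H2-Ab1 (-0.47), Rps2 (-0.47) and Hist1h2ap (-0.46). High values in the authors' deposited table were those of Apoa1 (0.56), Fabp6 (0.25), the chaperone Hsph1 (0.23), Guca2b (0.18), mt-Co1 (0.15), Mir6236 (0.15), the aminopeptidase Anpep (0.14), Jarid2 (0.14), Krt20 (0.13) and Camk1d (0.13). Proliferation genes had 26 of 31 members below the median of all genes (percentile 0.0), with Tuba1b at -0.42 and Ube2c at -0.29 in the authors' deposited table. Class II antigen presentation genes had 6 of 7 below (percentile 0.0), and the authors' deposited table gave the invariant chain Cd74 -0.40, H2-Aa -0.39 and H2-Eb1 -0.36. Class I antigen presentation genes (9 of 13 below, percentile 7.26) and antimicrobial genes (8 of 11 below, percentile 9.91) did not stand apart. Stem markers were low by the same measure (10 of 18 below, percentile 0.79), with Olfm4 at -0.42 and Smoc2 at -0.17 in the authors' deposited table.

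On the higher side in stem cells stood enterocyte markers (28 of 30 above, percentile 100), brush border and transport genes (21 of 25, 100), retinoid and xenobiotic genes (12 of 14, 99.9), p53 and apoptosis genes (9 of 11, 99.9), lipid absorption (13 of 22, 99.9), bile acid genes (7 of 9, 99.6), interferon-stimulated genes (5 of 7, 99.0) and secretory granule genes (8 of 12, 98.2). Heat shock genes had 10 of 14 above (percentile 100), although the authors' deposited table gave Hspa8 -0.37 against 0.23 for Hsph1. Oxidative phosphorylation genes stood above their matched lists (percentile 99.2) with 62 of 76 members below the median of all genes, and without matching they stood below (percentile 0.0). Apart from enterocyte markers (median 0.04), the lists on this side had medians under 0, from -0.0038 for brush border genes to -0.14 for oxidative phosphorylation. Ribosomal protein genes stayed within the limits (60 of 76 below, percentile 16.0). Secretory granule genes did not stand apart by their mean, stem markers did not without matching or with a detection floor, and lipid absorption did not with that floor. All 13 lists that did not stand apart lay between percentiles 5.21 and 94.5.

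In goblet cells, the mucus-secreting cells, enterocyte and Paneth cell transcripts were high in group 1 while the main mucin was nearly level. Muc2, the gel-forming mucin of the intestine (chromosome 7, 141690340 to 141754691), had a log2 fold change of -0.02 in the authors' deposited table, with detection in 97.4% of group 1 and 98.0% of group 2. Ramp1, a subunit of the receptor for the nociceptor peptide CGRP (chromosome 1, 91179822 to 91225196), was at 0.13 in the authors' deposited table, detected in 49.7% and 40.5% of cells. Outside goblet cells, at unknown depth, Muc2 was detected in 30.3% and 35.8% of enterocytes and in 22.2% and 28.6% of tuft cells in the authors' deposited table. The highest fold changes in the authors' deposited table were those of Apoa1 (1.29), the lysozyme gene Lyz1 (0.91), Fabp6 (0.79), the defensin Defa17 (0.58), Fabp2 (0.52), mt-Rnr1 (0.46), Anpep (0.45), Clca1 (0.43), Sprr2a2 (0.42) and Crip1 (0.38). The lowest in the authors' deposited table were Reg3g (-0.60), Rps2 (-0.57), Pdia5 (-0.46), Actg1 (-0.44), Ceacam10 (-0.44), Mmp7 (-0.43), Eef1a1 (-0.43), Rpl4 (-0.42), Reg3b (-0.41) and Rpl5 (-0.41).

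All 34 enterocyte markers listed in goblet cells were above the median of all genes (percentile 100), as were 25 of 26 brush border and transport genes (percentile 100) and all 9 bile acid genes (98.7). Paneth markers had 6 of 9 above (percentile 100), but the authors' deposited table placed the Paneth protease Mmp7 at -0.43 and Nupr1 at -0.22. Antimicrobial genes had 11 of 16 above (percentile 100), with Sprr2a2 at 0.42, and 5 members lay below, among them Reg3g, Reg3b and Pigr (-0.30) in the authors' deposited table. Retinoid and xenobiotic genes (9 of 12, 99.7), junction genes (19 of 28, 99.7), immediate early genes (13 of 19, 98.4) and mitochondrially encoded genes (7 of 13, 98.0) also stood on the higher side. Lower were ribosomal protein genes (58 of 73 below, percentile 1.38), tuft markers (5 of 6, 1.60) and class I antigen presentation genes (8 of 13, 2.29), with H2-D1 at -0.25 and H2-K1 at -0.22 in the authors' deposited table. By their mean, the retinoid, junction, immediate early, mitochondrial, tuft and class I lists no longer stood apart. Immediate early and mitochondrial genes did not without matching, and antimicrobial and class I genes did not with a detection floor. Goblet markers as a list did not stand apart (17 of 25 below, percentile 10.8), and its members went both ways in the authors' deposited table, with Clca1 at 0.43, Agr2 at -0.39 and Tspan13 at -0.31. Mucin glycosylation genes were near the middle of their matched lists (16 of 27 below, percentile 55.8), and St3gal4 was at 0.32 in the authors' deposited table. Genes of the CGRP receptor and cyclic AMP pathway did not stand apart either (3 of 6 above, percentile 89.5), with Gnas at -0.27 in the authors' deposited table. Unfolded protein response genes (20 of 24 below, percentile 4.35) and Notch genes (3 of 5 below, 17.4) were within the limits, as were all 15 lists not named as standing apart.

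In enteroendocrine cells, the hormone-secreting cells, the hormone genes Pyy and Sct were highest in group 1, and Tph1, Chga and Chgb were lowest. The authors' deposited table gave Pyy, the precursor of peptide YY (chromosome 11, 102106676 to 102107832), a log2 fold change of 1.62, with detection in 52.9% of group 1 and 27.5% of group 2. Secretin, Sct (chromosome 7, 141278329 to 141279174), was at 1.19 with detection in 85.3% and 72.5% in the authors' deposited table. Tph1, the enzyme that starts serotonin synthesis (chromosome 7, 46644641 to 46672537), was at -1.27 with detection in 20.6% and 45.0%, by the authors' deposited table. The granins Chga and Chgb were at -1.22 and -1.21 in the authors' deposited table, and Agr2 (-0.97), Reg4 (-0.92), Rab3c (-0.86), the ghrelin gene Ghrl (-0.79), Ceacam10 (-0.77), the tachykinin gene Tac1 (-0.71) and Rgs2 (-0.67) were the other low genes. The remaining high genes in the authors' deposited table were Tmsb4x (0.85), Myl7 (0.67), Lypd8 (0.60), Tff3 (0.57), Psmb3 (0.53), Rec114 (0.46), Atp5mpl (0.46) and Ywhaz (0.45). Hormone genes stood on the higher side (6 of 11 above, percentile 100), although 5 members lay below the median of all genes, Tph1 and Ghrl among them, and by their mean they did not stand apart (percentile 56.7). Enteroendocrine markers stood on the lower side (20 of 30 below, percentile 0.0). Ribosomal protein genes (60 of 73 above, percentile 100) and oxidative phosphorylation genes (54 of 75, percentile 99.8) were high, with Rpl32 at 0.44 and Cyc1 at 0.43 in the authors' deposited table. The other 25 lists lay between percentiles 4.40 and 96.8, enterocyte markers being the lowest of them (21 of 34 below). Muc2 was at -0.06 in the authors' deposited table.

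**Figure D2:**
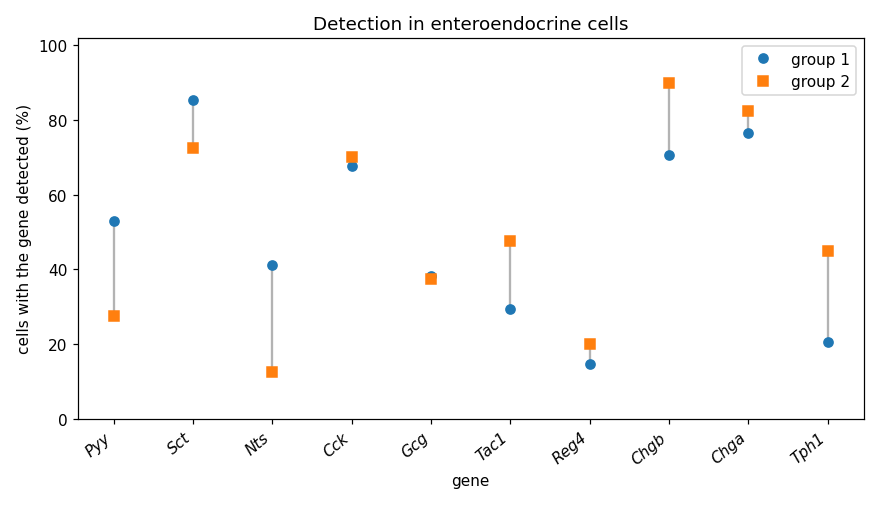
Share of enteroendocrine cells in which each gene was detected (vertical axis, percent) for 10 genes (horizontal axis), with circles for group 1 and squares for group 2, from the authors' deposited table, without replicate error. Pyy was detected in 52.9% and 27.5% of cells and Tph1 in 20.6% and 45.0%, while Gcg, at 38.2% and 37.5%, was nearly level. Nts, Cck and Gcg were chosen after their values were seen.

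In tuft cells, the chemosensory cells, the same lectins were lowest and enterocyte transcripts were again highest in group 1. The authors' deposited table gave Reg3b -1.87 and Reg3g -1.78, both detected in 100% of the cells of either group. Both genes were also detected in 100% of cells inside and outside cluster 0, of which they are markers, in the authors' deposited table, so in tuft, stem and goblet cells their values were not separated from free RNA. Further low genes in the authors' deposited table were Atpif1 (-1.60), Atp5g3 (-1.51), Rps13-ps2 (-1.47), Gpx2 (-1.36), Npm1 (-1.36), Lgals2 (-1.30), Krt19 (-1.30) and Rps3 (-1.28). High genes in the authors' deposited table were Apoa1 (1.59), Krt20 (1.42), Sprr2a2 (1.25), Polg2 (1.15), Tmem45b (0.93) and Smim24 (0.82). Tspan6, Cltc, Guca2b and Psmd4 were listed at 0 in group 2 and detected in 55.6%, 38.9%, 33.3% and 44.4% of group 1 in the authors' deposited table. Group 2 had only 8 distinct detection shares across all 6765 genes, and group 1 had 19, so detection was coarse in this sheet. Enterocyte markers (30 of 38 above), brush border and transport genes (20 of 26) and tuft markers (27 of 37) were each at percentile 100, and bile acid genes (5 of 7) were at 99.6, though only 0.10 above matched lists whose SD was 0.12. Tuft markers went both ways in the authors' deposited table, with Cd24a at 0.76, Il13ra1 at 0.56, Alox5 at -0.66 and Alox5ap at -0.54. Class II antigen presentation genes were at percentile 98.2 (4 of 7 above), a position lost under each of 3 other settings. Ribosomal protein genes (61 of 77 below, percentile 0.0) and oxidative phosphorylation genes (57 of 76, percentile 0.12) were low. Tuft effector genes (9 of 14 above, percentile 92.5) did not stand apart, nor did the other 21 lists. Muc2 was at 0.22 in the authors' deposited table.

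**Figure D3:**
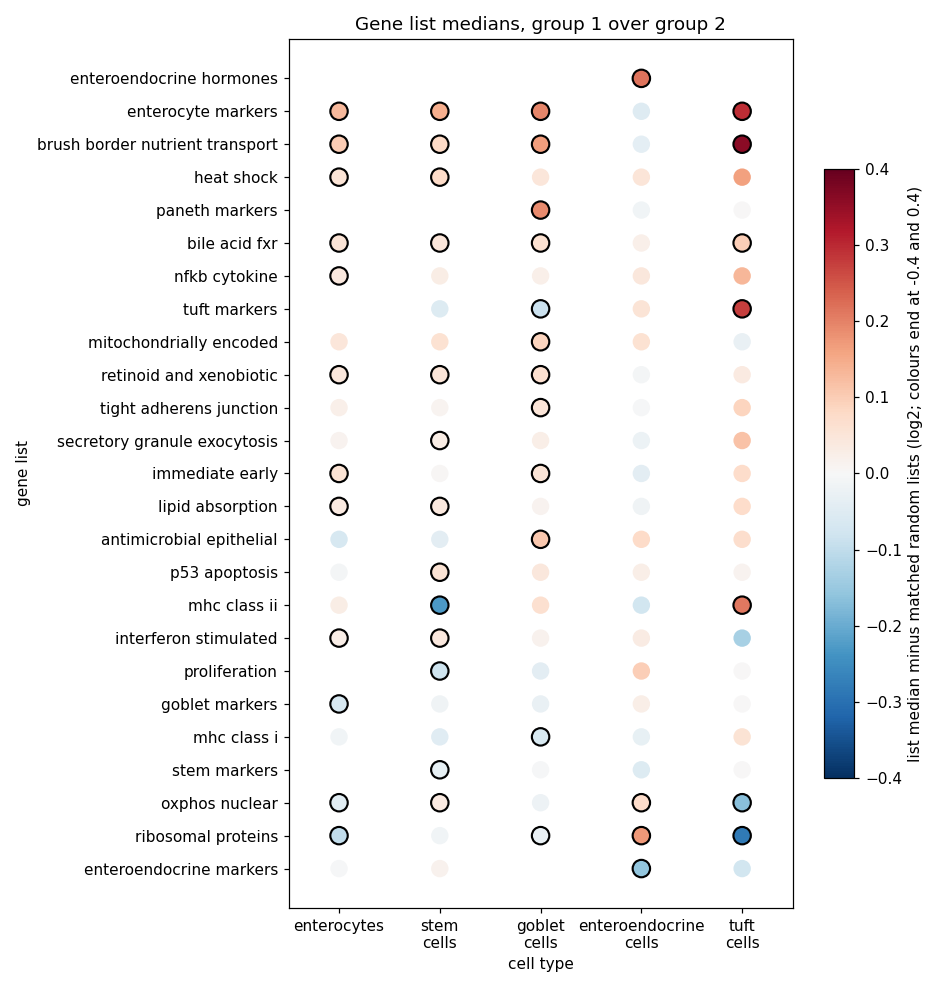
Median log2 fold change (group 1 over group 2) of each gene list minus that of matched random lists, as colour, for gene lists (vertical axis) in 5 cell types (horizontal axis). A black outline marks the 48 pairs that stood apart from 10000 random lists, and an empty place a list with fewer than 5 genes. Enterocyte markers were at percentile 100 in every cell type except enteroendocrine cells, where they were at 4.40.

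Fold changes of enterocytes, stem cells, goblet cells and tuft cells went together across genes, and those of enteroendocrine cells did not follow them. The Spearman correlation was 0.659 between enterocytes and stem cells over 1402 genes, 0.628 between enterocytes and goblet cells over 1383 and 0.539 between stem cells and goblet cells over 1860. With tuft cells it was 0.424 for enterocytes, 0.298 for goblet cells and 0.267 for stem cells. The 4 pairs with enteroendocrine cells gave between -0.103 and 0.029. In enterocytes and stem cells, 76.1% of genes lay on the same side of the median of their sheet, against 47.3% in enterocytes and enteroendocrine cells. These 10 correlations are across genes of the same 2 samples, so any difference between the samples is part of them, and all of them take the group order to be the same in every sheet.

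The marker table of the authors held 2096 entries for 8 clusters of cells of both genotypes together. In the authors' deposited table, cluster 4 was led by the goblet genes Tff3 (log2 fold change over all other cells 5.68), Zg16 (5.39), Spink4 (4.83), Fcgbp (4.72) and Agr2 (4.72), and 23 goblet markers were among its 282 genes. Cluster 6 was led in the authors' deposited table by Gcg (5.24), Pyy (5.13), Sct (4.97), Chgb (4.34) and Cck (4.09), with 24 enteroendocrine markers among 311 genes. The leading genes of cluster 7 included Krt18 (3.99), Sh2d6 (2.75), Cd24a (2.65) and Rgs13 (2.22) in the authors' deposited table, and the cluster held 28 tuft markers. Cluster 2 was led in the authors' deposited table by Ptma (2.15), Olfm4 (2.08) and the ribosomal genes Rpl14, Rpsa (1.64) and Rps3 (1.64), and it listed 70 ribosomal protein genes, 11 proliferation genes and 4 stem markers. Cluster 1, with 35 enterocyte markers, was led by 4933405D12Rik (2.98), Fabp2 (2.57), Apoa1 (2.41), Crip1 (1.46) and Clca4a (1.43) in the authors' deposited table. Cluster 0 was led in the authors' deposited table by Lypd8 (1.38), Reg3b (1.24), Krt19 (1.04), Plac8 (0.98) and Reg3g (0.87) and held 3 enterocyte markers. Zc3h7a (2.27), Itga9 (2.26), Gm26917 (1.29), Celf2 (1.28) and Safb (1.11) led cluster 3 in the authors' deposited table, with 7 enterocyte markers. Cluster 5, with 13 enterocyte markers, was led in the authors' deposited table by Gm42418 (3.84), an unnamed gene (2.96), AY036118 (2.46), Cdk8 (1.62) and mt-Rnr1 (1.13).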

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

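The 4 gene lists given here stood apart from matched random lists on the higher side in one cell type and on the lower side in another; the lists were fixed before the data were examined and this way of picking them out was chosen afterwards. The differences between cell types were not tested, since each genotype had 1 sample, and they take the group order to be the same in every sheet.

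Ribosomal protein genes lay 0.17 (log2) above matched lists in enteroendocrine cells and at -0.28 against them in tuft cells, a difference of 0.46. With the group order of the enteroendocrine sheet turned, they lay lower in both (-0.17 and -0.28), a difference of 0.11, and on the lower side in every cell type where they stood apart. Class II antigen presentation genes lay 0.21 above in tuft cells and at -0.23 in stem cells, a difference of 0.44, but the tuft side no longer stood apart under any of 3 other settings (percentiles 92.99 to 96.26). Tuft markers lay 0.28 above in tuft cells and at -0.09 in goblet cells, a difference of 0.36, but the goblet side rested on 6 genes and no longer stood apart by their mean (percentile 8.47). Nuclear oxidative phosphorylation genes lay 0.07 above in enteroendocrine cells and at -0.17 in tuft cells, a difference of 0.24. With that order turned the values were -0.07 and -0.17, a difference of 0.09, and only stem cells remained on the higher side, where the list changed sides without matching (percentile 0.0).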

How the results depend on the processing

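The zero point for the fold changes was an alternative chosen after seeing the data. With it placed at the fold change around which the deposited p-values are ordered, the share of well-detected genes higher in group 1 went from 34.3% to 79.0% in enterocytes, which turns the balance round. In tuft cells the share went from 29.6% to 40.7%. In stem and goblet cells it went from 6.90% to 99.2% and from 21.4% to 99.3%. There the point was not located and lay at the lower end of the fold changes, with 2 stem cell genes and 1 goblet cell gene below it. Nearly all genes lay above it by its placement, so these shares say nothing about the balance. The zero point was not moved in enteroendocrine cells, where 57.1% of well-detected genes lay above 0 and the order gave a rank correlation of 0.451 at best. With genes at or above the median detection, the share of all genes higher in group 1 was 5.81% in stem cells, 23.3% in goblet cells, 39.1% in enteroendocrine cells and 29.2% in tuft cells. At or above the upper quartile it was 24.6% in enterocytes, 5.33% in stem cells, 20.5% in goblet cells and 21.7% in tuft cells. These shares with a detection floor stayed under 50%, and the cause of the moves was not tested. With list members at or above the median detection, 7 lists stood apart in stem cells in place of 13 and 7 in goblet cells in place of 12; only 9 of these lists in either cell type kept at least 5 genes. Across the 48 lists that stood apart, 35 did so on the same side with the mean and 43 without matching. Of 39 that could be ranked with the detection floor, 33 did. Oxidative phosphorylation genes in stem cells changed side without matching (percentile 0.0), since strongly detected genes lie lower in that sheet (median of matched lists -0.18, of all genes -0.07). Between 17 and 19 of the 20 genes named by size in each cell type were named again at the upper quartile of detection. The median correlation over the 6 pairs without enteroendocrine cells was 0.481, and 0.414 with no floor, 0.542 at the upper quartile and 0.542 with Pearson. With 50 markers per cluster, 6 of 8 clusters had at least 3 markers of one cell type. No paired analysis was possible because each genotype had 1 sample. Tuft and enteroendocrine values are the most limited, since detection took few distinct values there.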

Other observations

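Markers of different clusters lay on different sides of the enterocyte sheet. The 240 markers of cluster 1, led by Fabp2 and Apoa1, had a median log2 fold change of 0.03, with 193 above the median of all enterocyte genes (percentile 100 of matched lists). The 127 markers of cluster 0, led by Lypd8 and Reg3b, had a median of -0.14, with 114 below it (percentile 0.0). The 70 markers of cluster 5 had 51 above (percentile 100), while the 90 markers of cluster 3 divided into 42 above and 48 below (percentile 95.8). Low positions were not particular to cluster 0: of the markers of clusters 2, 4, 6 and 7 in this sheet, 540, 155, 117 and 80 lay below and 65, 37, 67 and 41 above (percentiles 0.0, 0.0, 0.01 and 0.06). Among the 10 lowest enterocyte genes, Reg3g and Reg3b were leading markers of cluster 0. Zc3h7a, Itga9 and Safb were among those of cluster 3, and Cdk8 among those of cluster 5. Apoa1, Crip1 and Clca4a, among the 10 highest, were leading markers of cluster 1. The other genes of these 10 and 10 were not among the 5 leading markers of any cluster. Cluster shares per group are not given in the sources used here, so a different cluster mix was not separated from these values. These marker comparisons were chosen after seeing the data, and the clusters of the enterocyte sheet are not stated.

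In the goblet sheet, some Paneth and enterocyte transcripts differed in amount more than in detection, and neither free RNA nor doublets were separated from them. The authors' deposited table gave Lyz1 a log2 fold change of 0.91 with detection in 23.6% of group 1 and 22.1% of group 2, Defa17 0.58 with 25.1% and 26.5%, and Fabp2 0.52 with 46.2% and 49.0%. This was not particular to goblet cells. The authors' deposited table gave Apoa1 1.59 with 88.9% and 100% in tuft cells and 0.56 with 88.2% and 90.0% in stem cells.

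Of the tests in the following paragraphs, the relation of p-values to detection was set before its result was seen, and every other test was chosen only after the result was seen. Genotype is confounded with sample throughout, so a biological difference stays open and untested in each case.

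Enterocyte markers lay higher in group 1 in stem, goblet and tuft cells. A single scaling factor would move all genes alike but for the unknown offset of the scale. The list's percentile of 100 in goblet cells is part of the pattern itself, and lists were matched on detection and not on expression. That percentile is therefore no separate test of such a factor. Enterocyte RNA added to goblet droplets may account for part of the pattern: goblet fold changes exceeded enterocyte fold changes by a median of 0.12 over 34 markers, against -0.0011 in matched lists (percentile 100). Free RNA should reach enteroendocrine cells too, where the list's median minus that of matched lists was -0.0526 (SD of matched lists 0.0316), but that sheet went with no other and its group order is not stated, so more free RNA in group 1 cannot be told apart from its absence. Apoa1 and Fabp6, abundant enterocyte transcripts, were detected in 92.8% and 100% of group 1 goblet cells in the authors' deposited table. In group 2 goblet cells the shares were close to these, at 86.4% and 99.7% in the authors' deposited table. The sort for epithelial cells would not remove enterocytes.

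Among genes detected in at least 70% of both groups, the deposited p-values of enterocytes and tuft cells were ordered better around a fold change other than 0. In enterocytes, closeness to -0.18 ordered them with a rank correlation of 0.888, against -0.113 for closeness to 0, so p-values and fold changes may have been scaled differently. A one-sided test would order them by the signed fold change, which gave -0.656 there and 0.183 in tuft cells, where closeness to -0.20 gave 0.885 and closeness to 0 gave 0.687. In stem, goblet and enteroendocrine cells the signed fold change ordered the p-values as well as any zero point (-0.691, -0.830 and -0.451). A one-sided order and another scaling cannot be told apart there by the order alone. The labels name different tools for the sheets and for the fold change column, but not whether the test was one-sided. Detection alone gave -0.470 in goblet cells, smaller than the 0.830 from the fold change.

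In enteroendocrine cells, 2 lists written after the sheet was seen, called here enterochromaffin and L cell genes, moved apart by 0.88 (log2); the L cell list, not all of whose members are named here, holds genes that other enteroendocrine subtypes also express (Cck, Isl1, Nkx2-2, Nts, Pcsk2, Scg2 and Sct). The 10 enterochromaffin genes had a median of -0.68 (percentile 0.0) and the 13 L cell genes one of 0.21 (percentile 100). A single scaling factor would not move 2 lists apart, but lists written after the values were seen do not test it. A different mix of subtypes among the cells of both groups is a candidate explanation: detection moved as such a mix would need for 21 of 23 genes, all 10 enterochromaffin genes being detected less often in group 1 and 11 L cell genes more often (in the authors' deposited table Gcg was nearly level, at 38.2% against 37.5%, and Cck and Gpr119 were detected less often in group 1), in a sheet where 67.4% of all genes were detected less often in group 1. The lists include genes that drew attention to the pattern. Without those named by size, 14 of 16 moved that way, but these too were chosen after the sheet was seen. Among genes of this sheet whose detection differed by over 10 percentage points, detection and fold change had the same sign for 96.4%. The counts therefore largely repeat the split in fold changes and are no separate test of a mix. Detection took only 35 and 41 distinct values in this sheet, and chance sampling of cells was not tested.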
